A study of Mus musculus with 800 samples.

How the data were processed

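The data are read counts of 800 single nuclei, 40 for each of 20 vectors, per the labels all from the anterior lateral motor cortex of C57Bl/6J mice. The series design adds that the vectors were given at 5e11 vg per mouse, that nuclei were sorted 3 to 4 weeks later, and that striatum and visual cortex were sorted too. No sample label names either of these. Per the labels each library holds 1 nucleus, was made with SMART-Seq v4 and Nextera XT and was sequenced to about 0.5 M read pairs. SMART-Seq v4 makes full-length cDNA from polyadenylated RNA without molecule barcodes, so values count reads rather than molecules, amplification duplicates cannot be told from other copies, and values grow with transcript length, and the protocol does not keep the strand, so overlapping antisense RNA is not separated. STAR 2.7.2a and the mm10 mouse genome are named per the submitters' processing notes. The gene annotation, the counting rule, read trimming and the treatment of introns are not given in the sources used here.

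The authors deposited a table of counts with 32285 genes and 2501 nuclei, checked to hold whole numbers with a different sum in each nucleus. The 800 nuclei described by labels were matched by library name, 0 of them had values identical to another nucleus, and the other 1701 columns have no label and were not analysed here. Gene identifiers were matched to symbols for 32158 genes, 127 had none, and 52 symbols were shared by several identifiers. Gene positions come from the GENCODE M21 annotation of mm10, matched by identifier, which need not be the annotation the authors used. The table has no reporter sequence, so transgene reads could not be measured.

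Median depth was 260170 counts per nucleus (70 to 901264), and medians per vector ran from 209113 in AiE0078h to 314832 in AiE0779m. A median of 2576.5 genes was detected per nucleus, from 806 in AiE0410m to 3362 in AiE0475m. Summed counts per vector ran from 9467151 to 12192831, so 3 counts over such a sum, the floor for ratios, lie near 0.3 CPM (counts scaled to a library total of 1e6). For comparisons at equal depth each nucleus was thinned at random to 150000 counts, the 5th percentile of nuclei past the filter rounded down to a multiple of 10000, and 49 nuclei were too shallow.

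Nuclei with at least 1000 genes were kept (698, with 102 below). Counts were scaled to 1e+06 per nucleus, log transformed, and clustered with scanpy 1.11.5 and leidenalg 0.10.2 on 2000 variable genes, scaled with a cap of 10, with 30 principal components, 15 neighbours and a Leiden resolution of 1. The 427 genes of 17 fixed lists were kept out of the clustering, so that no list gene defined a class. A cluster took the name of the class whose fixed markers had the highest mean level relative to the highest cluster, with at least 3 markers detected in 25% of its nuclei and at least 1 marker of the class or of its subclasses among its top 10 genes by fold. GABAergic-like clusters of 96 and 28 nuclei met this only through Sst, a subclass marker. The markers and the minimum were fixed before the data were examined, while this scoring was settled after a first look at the clusters. Names end in "-like" because they rest on RNA alone. Subclasses were named in the same way after clustering glutamatergic-like and GABAergic-like nuclei again, and a cluster stayed unnamed where its best subclass had no marker among the top genes or fewer than another subclass. Recovery of the classes was tested on simulated data, where 698 of 698 nuclei returned to their class. Each simulated nucleus was drawn from the summed profile of its own class, without variation within a class. The result thus checks the procedure and not the class given to any real nucleus.

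The labels name no animal, so each vector is 1 sample. Shares have exact Clopper-Pearson and summed levels exact Poisson 95% intervals, both for counting error only, and vectors were not tested against each other. The Clopper-Pearson intervals treat nuclei as independent draws, although nuclei close in title number under a vector label tended to share a class. Cell classes were compared within vectors on summed counts, with vector as a block, in vectors with at least 3 nuclei of each class, by edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pairing comes from the vector label shared by both sums. Standard errors are the absolute log2 fold change over the square root of F. List genes are those counted, since other genes can define the clusters. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and at an estimated one. Library series S40326 (408 nuclei) and S40324 (312) were compared in vectors with at least 8 nuclei in each, and series S40323 (72) and S40325 (8) entered no such test. Genes detected were compared by an exact sign-flip permutation test over vectors. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

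Named genes were fixed by rule before the data were examined, and not every gene the rule names is printed. They are class markers, the 3 genes per vector with the largest ratio of summed CPM to the median of the other 19 vectors (a read in at least 25% of nuclei and at least 100 reads, without sex-linked, mitochondrially encoded and provisional genes), and in each contrast the 3 list members with the largest absolute log2 fold change past the threshold, up to 30 genes. Genes named outside this rule are marked as chosen after their values were seen. The lists cover interferon and antigen presentation, DNA damage and p53 targets, immediate early genes, viral entry and trafficking, heat shock, nuclear long noncoding RNA, potassium channels, sodium and calcium channels, ionotropic glutamate receptors, GABA-A receptors, synaptic vesicle release, glutamate and GABA uptake, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded and sex-linked genes.

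Alternatives were minimums of 500 and 2000 genes, resolutions of 0.5 and 2, 1000 and 4000 variable genes, a marker score per nucleus, single library series, thinned counts, gene lists left in the clustering, DESeq2 1.42.0, RLE scaling, no filter beyond 1 count, no vector block, at least 5 nuclei, each vector left out in turn, and mean levels over nuclei. Added after seeing the data were no minimum of genes, a minimum of 500 genes for the contrasts, runs of 8 title numbers as the unit, removal of runs with a striatal projection neuron-like nucleus, equal numbers of nuclei on both sides, and GABAergic-like nuclei alone for the library series. The fits were tested on simulated data with 200 genes changed by 2-, 4- or 16-fold, and recovery is among the changed genes that passed the filter (169 and 164 in the comparisons below): for GABAergic-like against glutamatergic-like nuclei edgeR recovered 0%, 15.8% and 61.8% of the changed genes with 2.27% false calls, and DESeq2 12.3%, 40.4% and 92.7% with 70.2% false calls. For non-neuronal-like against neuronal-like nuclei edgeR recovered 0%, 3.51% and 20.0% with 7.69% false calls, and DESeq2 gave 85.6% false calls. The simulated counts used dispersions estimated by edgeR. These rates hold for 200 changed genes and need not hold where many more genes differ.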

Results

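The labels describe 800 single nuclei from the anterior lateral motor cortex of C57Bl/6J mice, sorted for a yellow fluorescent protein fused to histone H2B that keeps the signal in the nucleus. The reporter was delivered by 20 adeno-associated virus vectors with the brain-penetrant PHP.eB capsid, and each vector holds its own promoter or enhancer and 40 nuclei. Among the vectors are hSyn1, a promoter active in neurons, CMV, a general viral promoter, and DLX2.0 and hI56i, which carry Dlx enhancers active in forebrain inhibitory neurons. The labels give the other 16 vectors a code without a target cell type. The comparisons concern which cells carried the reporter under each vector, and which genes differ between the cell classes that carried it.

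GABAergic-like nuclei, those with the genes of inhibitory neurons, were the most frequent class: 278 of the 698 nuclei with at least 1000 genes detected (39.8%, 95% interval 36.2 to 43.6%), present under all 20 vectors and the leading class under 10. Striatal projection neuron-like nuclei, with the genes of the inhibitory output cells of the striatum, made up 160 nuclei (22.9%, 19.9 to 26.2%) in 15 vectors although every nucleus is labelled as cortex. Glutamatergic-like nuclei, the excitatory neurons of cortex, made up 109 (15.6%, 13 to 18.5%), astrocyte-like nuclei 101 (14.5%, 11.9 to 17.3%) and oligodendrocyte-like nuclei, the myelin-forming cells, 50 (7.16%, 5.36 to 9.34%). The minimum of genes decides the last count: 125 of 790 nuclei were oligodendrocyte-like with a minimum of 500 genes, more than were astrocyte-like (112) or glutamatergic-like (109). The intervals here and below are exact Clopper-Pearson intervals that cover counting error only. These intervals treat nuclei as independent draws, which the classes did not bear out. Within runs of consecutive title numbers under a vector label, 67.7% of pairs shared a class, against 36% between runs of a label. The intervals can therefore be too narrow, for single vectors and for all nuclei together, by an amount that was not estimated. The labels name no animal, so each vector counts as 1 sample and no test was made between vectors.

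hSyn1 nuclei were all neuronal, 38 of 38 (100%, 90.7 to 100%): 27 glutamatergic-like (71.1%, 54.1 to 84.6%) and 11 GABAergic-like (28.9%, 15.4 to 45.9%). CMV nuclei were 56.8% neuronal (39.5 to 72.9%), with 18 of 37 glutamatergic-like (48.6%, 31.9 to 65.6%) and 16 of 37 astrocyte-like. Of these 16, 8 were the title numbers 33 to 40, which held no other class. Of the Dlx vectors, DLX2.0 held 24 GABAergic-like nuclei of 38 (63.2%, 46.0 to 78.2%), 9 astrocyte-like and 4 oligodendrocyte-like. Its glia were confined to the later title numbers. Numbers 25 to 32 held 8 of the 9 astrocyte-like nuclei, and numbers 33 to 40 all 4 oligodendrocyte-like nuclei. hI56i held 5 GABAergic-like nuclei of 27 and was led by 11 striatal projection neuron-like nuclei (40.7%, 22.4 to 61.2%). That lead depended on the minimum of genes, since with 500 genes or no minimum hI56i was led by oligodendrocyte-like nuclei, 17 of 40. It also depended on the library series, the batch given by the library names: the striatal projection neuron-like share of hI56i was 0% in series S40324 and 73.3% in series S40326.

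Among the enhancer codes, GABAergic-like nuclei were most frequent under AiE0452h (29 of 35, 82.9%, 66.4 to 93.4%), AiE0600m (28 of 40), AiE0475m (27 of 39) and AiE0401h (26 of 40), and also led AiE0078h (18 of 40), AiE0445h_3xC2 (16 of 34), AiE0140h (13 of 36), AiE0743m_3xC2 (14 of 40) and AiE0682h, where they tied with striatal projection neuron-like nuclei at 13 of 39. Striatal projection neuron-like nuclei led AiE0779m (21 of 31, 67.7%, 48.6 to 83.3%), AiE0387m (25 of 40, 62.5%, 45.8 to 77.3%), AiE0450h (17 of 39) and AiE0410m (7 of 12). The 7 of AiE0410m were all among title numbers 33 to 40. Astrocyte-like nuclei led AiE0390m (25 of 33, 75.8%, 57.7 to 88.9%) and AiE0391h (13 of 27), and oligodendrocyte-like nuclei led AiE0447h (16 of 33). AiE0410m lost 28 of its 40 nuclei to the minimum of 1000 genes, and with 500 genes or no minimum it was led by oligodendrocyte-like nuclei, 32 of 40. The higher minimum of 2000 genes removed most glia, leaving 11 astrocyte-like and 0 oligodendrocyte-like nuclei. The leading class was the same in 11 of 18 vectors with series S40324 alone and in 11 of 15 with series S40326 alone. In series S40324 and S40326, the share of the leading class was 100% and 6.25% for AiE0387m, 100% and 6.67% for AiE0391h, 100% and 16.1% for AiE0682h, and 100% and 18.8% for AiE0743m_3xC2.

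**Figure D1:**
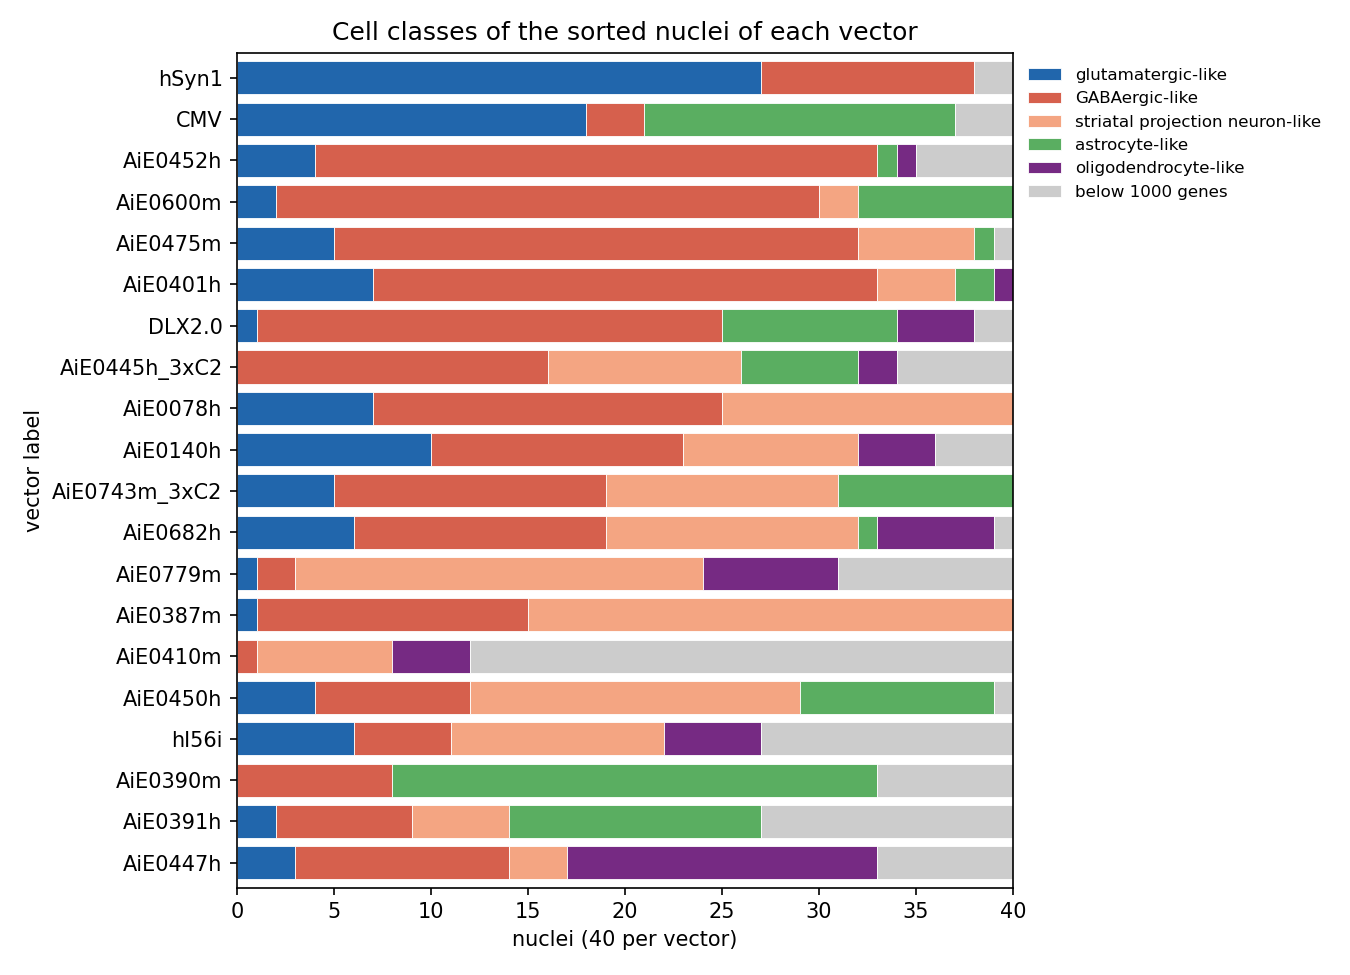
Number of nuclei in each cell class for the 20 vectors, ordered by leading class. Each bar adds up to the 40 nuclei of a vector, and grey marks nuclei with fewer than 1000 genes detected, which have no class.

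Within the GABAergic-like nuclei, Pvalb-like cells made up 127 of 278 (45.7%, 39.7 to 51.7%). Only a cluster of 68 of them had Pvalb among its top genes. Clusters of 39 and 20 were named through Tac1 and Erbb4, and through Pthlh. Sst-like cells, which express somatostatin, made up 77 (27.7%, 22.5 to 33.4%) and Lamp5-like cells 26 (9.35%, 6.20 to 13.4%), and 48 had no subclass name. Pvalb-like cells led the GABAergic-like nuclei of AiE0475m (21 of 27, 77.8%, 57.7 to 91.4%) and AiE0600m (19 of 28, 67.9%, 47.6 to 84.1%). Sst-like cells led those of AiE0452h (17 of 29, 58.6%, 38.9 to 76.5%) and AiE0401h (14 of 26, 53.8%, 33.4 to 73.4%), while DLX2.0 held 7 Pvalb-like, 7 Sst-like and 6 Lamp5-like among 24. Of the 109 glutamatergic-like nuclei, 34 were L2/3 IT-like, the upper-layer neurons that project within the cortex, 12 were L5 ET-like, the deep neurons that project out of it, and 63 had no subclass name. The L2/3 IT-like share depended on the clustering, from 0% at a Leiden resolution of 0.5 to 42.2% with a marker score per nucleus.

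Summed marker levels per vector are given with exact Poisson intervals that cover counting error. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, was highest in hSyn1 (261 CPM, 251 to 272) and CMV (224, 215 to 232). Gad1, which makes GABA, was highest in AiE0475m (826 CPM, 809 to 844) and AiE0600m (750, 734 to 766), and was 19.8 CPM in CMV. Rgs9, a striatal regulator of G protein signalling, was highest in AiE0779m (802 CPM, 786 to 818) and had no count in AiE0390m. Slc1a3, the astrocyte glutamate transporter, was highest in AiE0390m (2738 CPM) and AiE0391h (2601), and Mog, a myelin protein, was highest in AiE0410m (1445 CPM) and had no count in hSyn1.

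The genes with the largest ratio to the median of the other 19 vectors follow. Slc38a3, a glutamine transporter, reached 712 CPM in AiE0390m. The median of the other 19 vectors was 0, so the ratio of at least 2492-fold is against a floor of 3 counts over the summed depth of a vector. It is not a fold over each other vector. Fgfr3, a growth factor receptor, was 989 times the median of the other vectors in AiE0390m, 567 times in CMV and 538 times in AiE0391h. Among vectors with neurons in the lead, Tbr1, a transcription factor of excitatory cortical neurons and one of the class markers, was 33.9 times the median in hSyn1, Lhx6, a transcription factor of Pvalb and Sst interneurons, 14.1 times in AiE0401h, and Htr2c, a serotonin receptor, 11.7 times in AiE0387m. In vectors led by neurons, Gpr37l1, an astrocyte receptor, was 24.7 times the median in AiE0450h, and Ntsr2, another, 17.2 times in AiE0743m_3xC2. Of the 60 leading genes, 3 per vector, 38 were also named by the mean over nuclei.

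Glia yielded fewer genes than neurons in each of the 15 vectors with at least 3 nuclei of both. At an equal depth of 150000 counts, the median number of genes per nucleus was 1268 in non-neuronal-like and 2834 in neuronal-like nuclei as a mean over 15 vectors, a difference of -1566 (SD 230), lower in 15 of 15 vectors (exact sign-flip permutation p = 6.1e-05, the smallest the test can give). GABAergic-like nuclei had 2973 genes and glutamatergic-like nuclei 3108, a difference of -135 (SD 297) over 12 vectors, lower in 8 (exact p = 0.139). Per class, the median was 3116 genes in glutamatergic-like, 3041 in GABAergic-like, 2591 in striatal projection neuron-like, 1368 in astrocyte-like and 1080 in oligodendrocyte-like nuclei. Only nuclei with at least 1000 genes entered, so the minimum cut off the lower end of the glia and raised their medians. With no minimum, 76 of the 102 nuclei left out were named oligodendrocyte-like.

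Compared with glutamatergic-like nuclei of the same vectors, GABAergic-like nuclei held less RNA of several activity-dependent genes, and some ion channel and receptor genes differed either way. Homer1 (chromosome 13, 93299635 to 93405129, mm10), a synaptic scaffold gene induced by activity, had 34.1 CPM (SD 27.7) in GABAergic-like and 294 (SD 146) in glutamatergic-like sums and was lower in 12 of 12 vectors. Grik1 (chromosome 16, 87895900 to 88290265), a kainate receptor subunit, had 231 (SD 161) against 0.885 CPM, and Kcns3, a potassium channel subunit, 153 (SD 123) against 0.944, each higher in 12 of 12 vectors. Malat1 (chromosome 19, 5795690 to 5802672), an abundant nuclear RNA, was lower in 12 of 12 vectors, with 142343 (SD 11277) against 216081 (SD 34877) CPM.

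Of 343 genes measured from the fixed lists, 19 differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all 9146 genes, 5 higher and 14 lower in GABAergic-like nuclei, and the median log2 fold change of all genes was 0.38. Among all genes, which include those that define the clusters, the balance was the other way, with 271 called, 152 higher and 119 lower. Of 8 immediate early genes, which respond to activity, 3 were lower and 0 higher: Bdnf, a growth factor (2.13 against 78.8 CPM, lower in 10 of 12 vectors and higher in 0, log2 fold change -7.89, SE 1.70), Arc (13.1 against 263 CPM, lower in 10 and higher in 2, -7.10, SE 1.71) and Homer1 (-3.36, SE 0.59, adjusted p = 0.00089 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). For each of the 19 genes the fitted change is larger than the ratio of the mean CPM. Adjusted over the list alone there were 4. The list was lower as a group by camera (adjusted p = 4.3e-08), a call lost with an adjusted p = 0.0764 with an estimated correlation.

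Of 22 voltage-gated potassium channel genes, 2 were higher and 4 lower (9 adjusted over the list alone). Kcns3 (log2 fold change 9.52, SE 1.27) and Kcnc1, which serves fast spiking (548 against 90.5 CPM, chosen after its values were seen), were higher, and Kcnv1 (2.44 against 140 CPM, -8.62, SE 1.34) and Kcnh3 (2.75 against 82.3 CPM, -6.25, SE 1.59) lower. Of 23 sodium and calcium channel genes, the calcium channel subunit Cacna2d2 was higher (62.2 against 2.21 CPM), Cacna2d1 (54.6 against 373) and Cacna1e (130 against 446) lower, with 4 adjusted over the list alone. Of 15 ionotropic glutamate receptor genes, Grik1 was higher (log2 fold change 9.98, SE 1.01, adjusted p = 3.7e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the AMPA subunit Gria2 (-0.65, SE 0.18) and the NMDA subunit Grin2b (-0.90, SE 0.21) lower, again with 4 over the list alone. With equal numbers of nuclei 14 of the 19 list genes called were tested, and 12 of them were called. Cacna1e (-2.36, adjusted p = 0.0894 by edgeR's quasi-likelihood test) and Grin2b (-0.98, adjusted p = 0.0538 by that test) lost their calls. Bdnf, Kcns3, Kcnv1, Kcnh3 and Cacna2d2 were not tested in that fit.

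Of 8 nuclear long noncoding RNAs, Miat (177, SD 85.1, against 727, SD 196, CPM) and Malat1 (log2 fold change -0.70, SE 0.07) were lower, with 4 adjusted over the list alone. Of 24 synaptic vesicle genes, Stx1a, a membrane fusion protein, was lower (19.7 against 245 CPM), with 8 over the list alone. Of 83 oxidative phosphorylation genes, 1 was higher, the cytochrome c oxidase subunit Cox6a2 (55.1 against 4.61 CPM), and the list was higher by camera (adjusted p = 0.00151), a call lost with an adjusted p = 0.994 with an estimated correlation. Glutamate and GABA uptake had 0 of 9 genes past the threshold and 3 adjusted over the list alone. No gene passed in either way among 6 interferon and antigen presentation, 8 DNA damage, 20 viral entry and trafficking, 10 heat shock, 11 GABA-A receptor, 12 cholesterol synthesis, 76 ribosomal protein, 4 mitochondrially encoded and 4 sex-linked genes.

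The count of 19 list genes, 5 higher and 14 lower, depended on the fit, and so did its balance. It was 66 with DESeq2 (39 higher, 27 lower), 29 with no filter beyond 1 count (14 and 15), 27 without CMV (14 and 13), 12 without AiE0475m (4 and 8), 22 with RLE scaling (8 and 14) and 9 with runs of 8 nuclei as the unit (1 and 8). In the 6 vectors left after runs with a striatal projection neuron-like nucleus were removed it was 4 (2 and 2). The median log2 fold change of all genes was -0.49 with runs as the unit and -0.08 with equal numbers of nuclei. The p-values measure the spread between sums per vector, which are not known to come from separate animals.

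**Figure D2:**
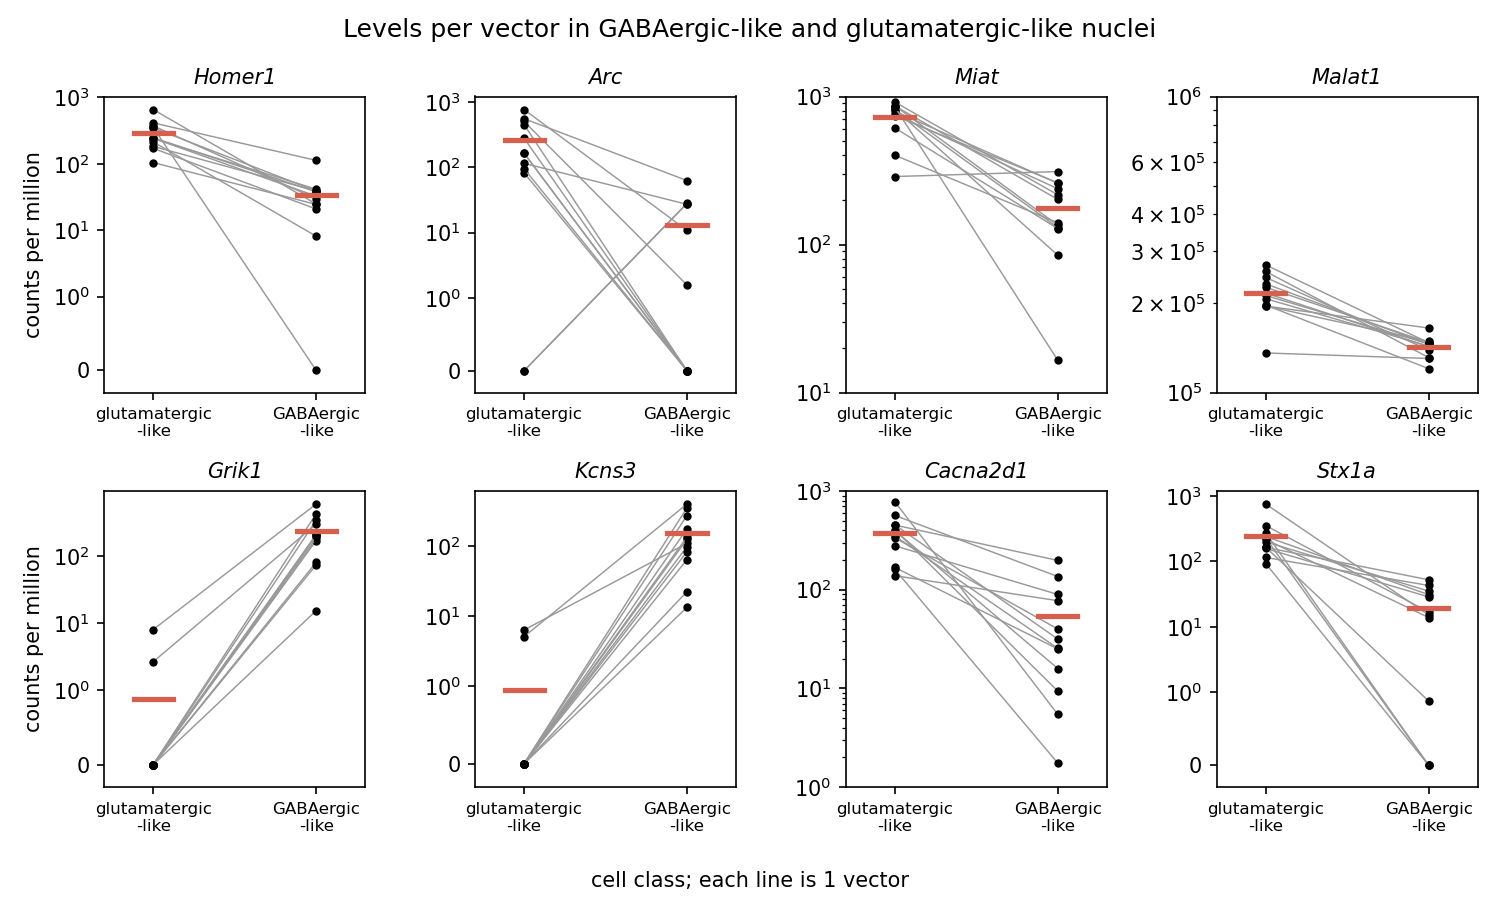
CPM of 8 list genes in the summed glutamatergic-like and GABAergic-like nuclei of 12 vectors. Lines join the sums of a vector, red bars are means over vectors, and axes that show 0 are linear below 1 CPM.

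Non-neuronal-like nuclei, the astrocyte-like and oligodendrocyte-like nuclei together, held little of the RNA that marks neurons. Meg3 (chromosome 12, 109541001 to 109571726), a noncoding RNA of an imprinted gene cluster, had 75.2 CPM (SD 211) against 11589 (SD 2351) in neuronal-like nuclei, and Snhg11 60.9 (SD 192) against 13100 (SD 2491), each lower in 15 of 15 vectors. Higher were Glul (chromosome 1, 153899944 to 153909723), the glutamine synthetase of glia, with 651 (SD 221) against 14.4 CPM in 15 of 15 vectors, and Neat1 (chromosome 19, 5824708 to 5845478), a nuclear RNA of paraspeckles, with 1790 (SD 2080) against 10.9 in 14 of 15. Msmo1 and Fdft1, enzymes of cholesterol synthesis, had 1300 (SD 900) against 156 and 289 (SD 179) against 46.6 CPM. These 4 higher genes were chosen after their values were seen.

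Of 346 list genes, 129 differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all 9528 genes, 5 higher and 124 lower. Among all genes 4391 were called, 176 higher and 4215 lower. The median log2 fold change of all genes was itself -3.71 (-3.46 with RLE scaling, -2.14 with no filter beyond 1 count, -1.95 with equal numbers of nuclei, -1.66 without runs holding striatal projection neuron-like nuclei and -0.70 without the vector block), and 119 of the 124 lower genes lay below that median. In 107 of the 124 the mean CPM in non-neuronal-like nuclei was at most 50% of the neuronal mean, and in 6 of the 129 the fitted change and the ratio of means had opposite signs, so levels are given here beside or in place of fitted folds.

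Ion channels and synaptic genes made up most of the lower genes. Of 18 potassium channel genes 17 were lower, among them Kcnc2 (3.16 against 173 CPM) and Kcns3, which had no count in non-neuronal-like nuclei and was at least 1078-fold lower against a floor of 3 counts over the group. Of 20 sodium and calcium channel genes 18 were lower, such as Cacna1e (1.53 against 345 CPM) and Cacna1a (2.66 against 166). Both lists were lower by camera (adjusted p = 1.2e-05 for potassium, 3.8e-08 for sodium and calcium channels), and an estimated correlation left an adjusted p = 0.0385 for each. Over the list alone 17 and 19 passed.

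Lower were also 11 of 13 ionotropic glutamate receptor genes (12 adjusted over the list alone), with Gria4 at 9.52 against 469 CPM, 9 of 12 GABA-A receptor genes (9), with Gabrb2 at least 1112-fold lower against the same floor, and 23 of 25 synaptic vesicle genes (23), with Rims1 at 1.07 against 136. Camera called the 3 lists lower (adjusted p = 0.000217, 0.00359 and 5.4e-06), and each call was lost, with adjusted p = 0.107, 0.151 and 0.148 with an estimated correlation. Of 9 nuclear long noncoding RNAs, 6 were lower and Neat1 higher (7 over the list alone), with Rian at 2.63 against 671 CPM.

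Of 16 cholesterol synthesis genes, 2 were higher, Msmo1 (log2 fold change 2.51, SE 0.69) and Fdft1 (2.46, SE 0.92, adjusted p = 0.0288 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 1 adjusted over the list alone. The list was higher than other genes by camera (adjusted p = 8.1e-09, and adjusted p = 0.0494 with an estimated correlation). Of 9 uptake and glutamine cycle genes, Glul was higher and 4 were lower (5 over the list alone). Of 7 interferon and antigen presentation genes, 3 were lower, among them Irf9 (1.43 against 21.2 CPM), and H2-K1, a major histocompatibility gene whose sequence is close to that of related genes, was higher (120, SD 138, against 6.64, in 13 of 15 vectors), with 4 over the list alone.

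Camera placed the interferon (adjusted p = 0.0279), oxidative phosphorylation (0.0451) and mitochondrially encoded (0.00200) lists higher than other genes while their median log2 fold changes were -0.35, -1.23 and -0.10, above the median of all genes. Each call was lost, with adjusted p = 0.197, 0.645 and 0.343 with an estimated correlation. Of 83 oxidative phosphorylation genes 7 were lower (6 over the list alone), of 7 mitochondrially encoded genes 0 passed in either way. Lower were also 5 of 8 immediate early genes (6 over the list alone), such as Nr4a1 (12.8 against 58.3 CPM) and Egr1 (27.1 against 133). The same held for 5 of 20 viral entry and trafficking genes (4), 12 of 76 ribosomal protein genes (2) and 0 of 4 sex-linked genes. Of 10 heat shock genes 2 were lower (2), Hsph1 at 27.2 against 116 CPM and Dnajb1 at 37.6 against 38.5. Of 9 DNA damage genes 2 were lower (1), with Plk2 at 17.4 against 247. Among all 9528 genes 4215 were lower, a larger share than in these lists, oxidative phosphorylation included and immediate early genes excepted. With equal numbers of nuclei the lower genes were 2 immediate early (Egr1 had an adjusted p = 0.175 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 2 viral entry and trafficking, 2 heat shock, 1 ribosomal protein, 1 DNA damage, 3 oxidative phosphorylation and 0 interferon genes. In that fit Stat2 had an adjusted p = 0.108, Irf9 and H2-K1 were not tested, and Ifi27 (log2 fold change 5.63, SE 2.08) and mt-Co1 (3.29, SE 1.13) were higher, both chosen after their values were seen.

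The count of 129 was 199 with DESeq2, 71 without the vector block, 78 with equal numbers of nuclei on both sides of each vector, 37 with runs of 8 nuclei as the unit and 54 in the 9 vectors left after runs with a striatal projection neuron-like nucleus were removed. In simulated data with these numbers of nuclei, edgeR recovered 20% of 16-fold changes. That simulation changed 200 genes, whereas 4391 were called among all genes here, so its recovery need not hold for this contrast.

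**Figure D3:**
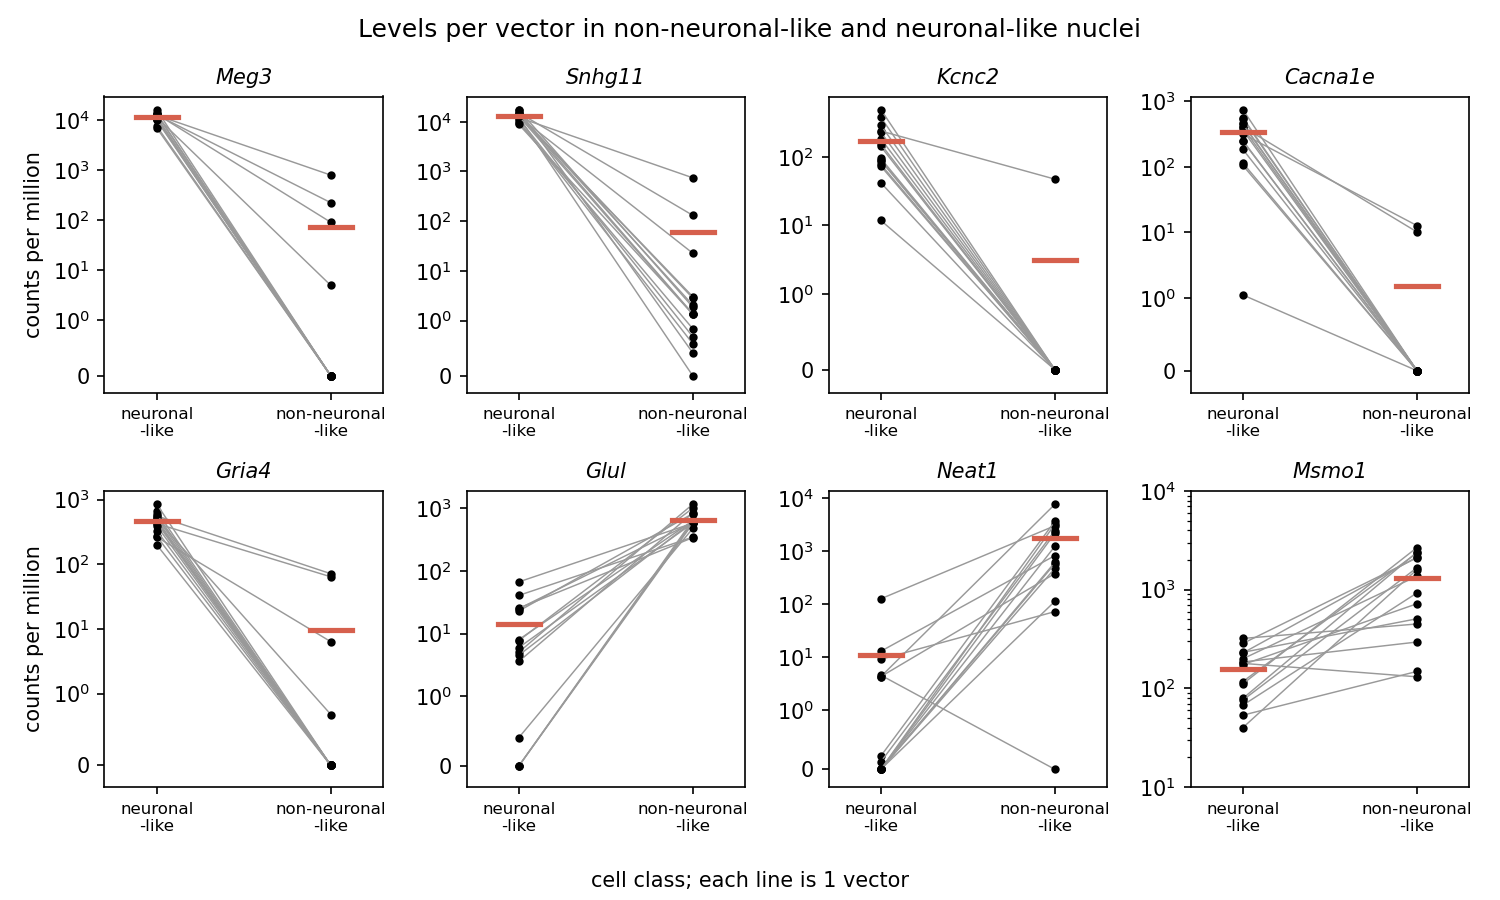
CPM of 8 list genes in the summed neuronal-like and non-neuronal-like nuclei of 15 vectors. Lines join the sums of a vector, red bars are means over vectors, and axes that show 0 are linear below 1 CPM.

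Between library series S40326 and S40324, compared within 11 vectors that held at least 8 nuclei in each, edgeR's quasi-likelihood test called 0 of 10647 genes. At an unadjusted p under 0.05 there were 586 genes, and DESeq2 called 948, of which 933 were higher in S40326. The median log2 fold change of all genes was 0.67, and 0.13 with equal numbers of nuclei. In GABAergic-like nuclei alone, over 7 vectors, edgeR also called 0 genes, with 189 at an unadjusted p under 0.05.

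The order of the nuclei in the titles separated classes more sharply than the vector label. In runs of 8 consecutive numbers under a vector label, 31 of the 88 runs with at least 5 nuclei past the filter held a single class, and 16 of 20 vectors had runs led by different classes. Under AiE0387m, numbers 1 to 24 were all striatal projection neuron-like and numbers 33 to 40 all GABAergic-like. Under AiE0600m, numbers 9 to 16 were all astrocyte-like among runs led by GABAergic-like nuclei, and under DLX2.0 numbers 25 to 32 were all astrocyte-like. Pairs of nuclei within a run had the same class in 67.7% of pairs, against 36% between runs of a label and 25.2% between labels.

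**Figure D4:**
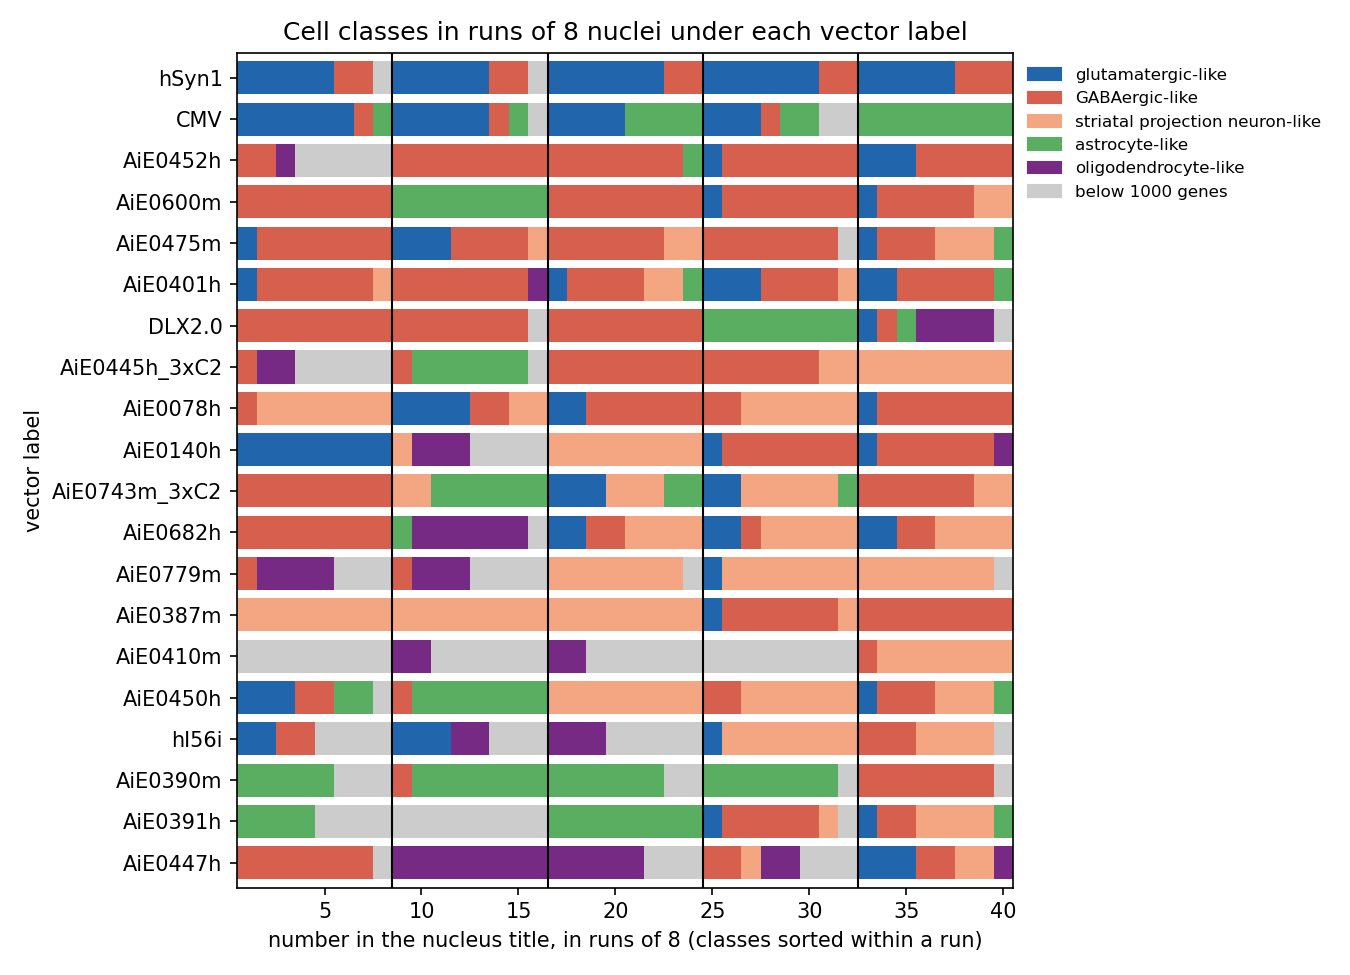
Cell classes in runs of 8 consecutive title numbers under each vector label. Classes are sorted within a run, so only the composition of a run is shown, and grey marks nuclei with fewer than 1000 genes detected.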

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

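Naming the nuclei below 1000 genes without that minimum was chosen after the results were seen. The 102 nuclei with fewer than 1000 genes detected enter no comparison above, and they hold a clear signal of myelin-forming cells. Mog (chromosome 17, 37010743 to 37023398), a myelin protein, reached 1323 CPM in their sum (95% Poisson interval 1309 to 1338), far above the 0.122 that 3 counts over the sum allow, and 54.9% of these nuclei had a read of it. With no minimum of genes, 76 of the 102 were named oligodendrocyte-like, among them 28 of 28 under AiE0410m, 12 of 13 under hI56i and 7 of 9 under AiE0779m. No explanation was tested for this signal. The oligodendrocyte-like nuclei past the minimum also had the fewest genes of the 5 classes, 1080 at equal depth.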

How the results depend on the processing

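The fits with the minimum of 500 genes, runs of 8 nuclei as the unit, runs with striatal projection neuron-like nuclei removed, equal numbers of nuclei and GABAergic-like nuclei alone, all settings of the striatal projection neuron-like comparison, and the shares with no minimum of genes were chosen after seeing the data. No list gene called both in a reported fit and under a setting had opposite signs, but balances did turn. For GABAergic-like against glutamatergic-like nuclei, more genes were higher than lower with DESeq2 (39 and 27) and without CMV (14 and 13), and the median log2 fold change of all genes went from 0.38 to -0.49 with runs as the unit and -0.08 with equal numbers of nuclei. For striatal projection neuron-like against GABAergic-like nuclei, 19 higher and 21 lower became 22 and 19 with no replicate block, 19 and 16 with 500 genes and 17 and 15 with equal numbers. The leading class turned in 2 vectors each with 500 genes and no minimum (AiE0410m, hI56i) and a marker score (AiE0682h, AiE0743m_3xC2), 3 with 2000 genes, 1 with thinned counts (AiE0078h), 7 with series S40324 and 4 with S40326. GABAergic-like nuclei led 8 to 13 vectors across the settings. Shares of the leading class stayed within their 95% interval in 20 of 20 vectors at resolutions of 0.5 and 2, with 1000 and 4000 variable genes, thinned counts and gene lists left in, in 19 with a minimum of 500 genes, no minimum or a marker score, in 12 with 2000 genes, in 7 of 18 with series S40324 alone and in 10 of 15 with series S40326 alone. With 2000 genes the shares moved to 0% (AiE0390m astrocyte-like), 87.5% (AiE0410m striatal), 89.5% (CMV glutamatergic-like), 95% (DLX2.0 GABAergic-like), 7.14% (AiE0391h astrocyte-like), 0% (AiE0447h oligodendrocyte-like), 89.7% (AiE0600m GABAergic-like) and 87.0% (AiE0779m striatal), since that minimum left 11 astrocyte-like and 0 oligodendrocyte-like nuclei. AiE0410m moved to 17.5% with 500 genes and 17.5% with no minimum, and AiE0401h to 45.0% with a marker score. Series S40324 alone gave 12.5% for AiE0078h, 0% for AiE0140h, 87.5% for AiE0475m, 100% for AiE0387m, 100% for AiE0391h, 0% for hI56i, 0% for AiE0450h, 0% for AiE0447h and 100% each for AiE0682h, AiE0600m and AiE0743m_3xC2. Series S40326 alone gave 6.25% for AiE0387m, 6.67% for AiE0391h, 73.3% for hI56i, 16.1% for AiE0682h and 18.8% for AiE0743m_3xC2, with fewer nuclei in each, and the cause was not tested. The Sst-like share was 34.2% at a resolution of 0.5 and 35.3% by marker score, and the L2/3 IT-like share 0% at 0.5, 19.3% at 2 and 42.2% by marker score, where the cause was not tested.

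List genes called numbered 19 for GABAergic-like against glutamatergic-like nuclei, 66 with DESeq2, 29 with no filter beyond 1 count, 9 with runs as the unit, 4 without runs holding striatal nuclei (fewer vectors), 12 to 27 leaving out each vector (12 without AiE0475m), and 16 to 22 under the other 7 settings. For non-neuronal-like against neuronal-like nuclei, 129 became 199 with DESeq2, 78 with equal numbers, 37 with runs as the unit, 54 without runs holding striatal nuclei, 115 to 146 leaving out each vector, 71 with no replicate block, and 97 to 155 under the other 6 settings. For striatal projection neuron-like against GABAergic-like nuclei, 40 became 115 with DESeq2, 61 with no filter, 14 with runs as the unit, 34 to 42 leaving out each vector, and 32 to 44 under the other 7. The library series gave 0 by edgeR (586 at an unadjusted p under 0.05), 948 with DESeq2 and 7 with no filter. DESeq2 made 68.3% to 85.6% false calls in simulated data of these designs with 200 genes changed, and otherwise the cause was not tested. In simulated sums with the depth and nuclei of these designs, edgeR recovered 61.8%, 20% and 58.3% of 16-fold changes, and 15.8%, 3.51% and 8.77% of 4-fold changes, in the 3 class comparisons. Both sets of rates depend on the number of changed genes, so they do not give the share of false or missed calls in the real data. With thinned counts the calls were 17, 113 and 38. With an estimated correlation, lists called by camera numbered 0, 3 and 1 for the 3 class comparisons. Genes detected kept their side of the threshold, at -177 and -61.5 for GABAergic-like minus glutamatergic-like. The reporter is not in the table, so its alternative was not run.

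The vector pairs both sums of a comparison. With no replicate block the counts were 22 for GABAergic-like against glutamatergic-like (18 shared with the blocked fit), 71 for non-neuronal-like against neuronal-like (71 shared), 41 for striatal projection neuron-like against GABAergic-like nuclei and 0 for the library series.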

Other observations

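The comparison of striatal projection neuron-like with GABAergic-like nuclei, the fits on equal numbers of nuclei and the 3 tests and the shuffles on runs of nuclei were chosen after the results were seen. Striatal projection neuron-like nuclei held more RNA of activity-dependent genes than the GABAergic-like nuclei of the same 12 vectors. Egr1 (chromosome 18, 34859823 to 34864984), a transcription factor induced by activity, had 247 CPM (SD 97.4) against 30.03 (SD 40.5), Arc 200 (SD 159) against 15.5, Junb 255 (SD 146) against 30.9, and Homer1 314 (SD 191) against 49.1, each higher in 12 of 12 vectors. Of 8 immediate early genes 4 were higher (5 adjusted over the list alone), and camera called the list higher (adjusted p = 1.8e-07, and adjusted p = 0.00378 with an estimated correlation). Of 339 list genes 40 differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 19 higher and 21 lower, where the median log2 fold change of all genes was -0.67. The GABAergic-like sums also serve the comparison with glutamatergic-like nuclei, so the immediate early genes of both comparisons share their GABAergic-like values.

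Ion channels differed both ways. Of 23 sodium and calcium channel genes 6 were higher and 1 lower (9 adjusted over the list alone): Scn4b (chromosome 9, 45138395 to 45154152), a sodium channel subunit, had 235 CPM (SD 118) against 11.5, Cacna1h 104 (SD 67.4) against 8.26, and Cacna1g, a low-threshold calcium channel, 2.74 against 72.7. Camera called that list higher (adjusted p = 0.000116), a call lost with an adjusted p = 0.264 with an estimated correlation. Of 19 potassium channel genes 2 were higher and 4 lower (10 over the list alone), with Kcnh3 at 83.6 against 8.01 CPM, Kcnc2 at 3.04 against 227, and Kcns3 without a count, at least 1209-fold lower against a floor of 3 counts over the group. Grik1 also had no count in striatal projection neuron-like nuclei and was at least 2131-fold lower. Of 14 ionotropic glutamate receptor genes 4 were higher and 2 lower (8), of 11 GABA-A receptor genes 2 were lower (2), and of 25 synaptic vesicle genes 1 was higher and 4 lower (8), with Syp at 75.6 against 298. Of 8 nuclear long noncoding RNAs 1 was higher and 4 lower (5), with Miat at 2.17 against 169 CPM and Meg3 at 8460 against 13862.

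Of the other lists, 1 of 6 interferon genes was lower (Ifi27, no count, at least 256-fold lower, 4 over the list alone), Plk2 was higher at 474 against 103 CPM and Gadd45a lower among 7 DNA damage genes (2), Hspa8 was lower among 10 heat shock genes (2) and Cox6a2, without a count, at least 606-fold lower among 83 oxidative phosphorylation genes (1). No gene passed among 19 viral entry, 9 uptake, 11 cholesterol synthesis, 76 ribosomal protein, 6 mitochondrially encoded and 4 sex-linked genes. Homer1 was chosen after its values were seen, and the other genes follow the rule for named genes. On simulated data with these vectors and 200 genes changed, edgeR recovered 58.3% of 16-fold changes, with 0% false calls.

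The striatal projection neuron-like nuclei, 160 of 698, are labelled as cortex. Interneurons named wrongly from shared inhibitory genes are argued against by 15 striatal genes held out of the class markers. By a marker score, 15 of 15 were higher than in GABAergic-like nuclei, with a median ratio of 19.1 (2.37 to 53.5). Penk and Tac1 among them are subclass markers, which that score does not use. The 15 include Penk at 2500 against 116 CPM, Foxp1 at 705 against 32.3 and Gpr6 at 261 against 12.2, and 4 of the 15 are also expressed in cortex. In the striatal projection neuron-like nuclei, the markers of 4 other classes were low. The highest, Aqp4, reached 0.0172 of the level in its own class (7.06 against 410 CPM). Mog had 0 counts and Nxph1 had 2 counts. These markers also served to name the classes, so nuclei rich in them would tend to be named otherwise. Striatal RNA in wells of other cells is therefore not decided by them. A candidate explanation is that these nuclei come from striatal tissue, which the series design names but the labels of these samples do not, and no value here tests whether dissection or the region label accounts for it.

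Cell class varied between runs of 8 title numbers under a vector label. Random mixing of the nuclei of a label is argued against by the same-class share of pairs, 31.7 points higher within runs than between runs of a label, the difference that made the pattern visible, against at most 4.01 points in 1000 shuffles of the nuclei of each label over its runs. Library series are argued against by a share 29.6 points higher within runs than between runs of the same label and series. Whether vector labels are out of step with the order of the nuclei stays open, although the first shares below go with it. Neighbouring runs with different labels in a library series shared a class in 41.7% of pairs. Runs of a label that are not neighbours shared it in 27.1% within a series, and in 30.3%, 11.4 points below the 41.7%, over all series. Neighbouring runs of the same label shared it in 56.6%. Labels out of step could leave such neighbours alike as well, so that share does not decide the question. Sorting by plate, which the labels do not give, or from a region other than the labelled one also stays open, and no biological explanation was tested.

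The list genes called between non-neuronal-like and neuronal-like nuclei were nearly all lower in non-neuronal-like nuclei, which were fewer. Fewer nuclei as the whole cause are argued against by the fit on equal numbers, where 92.3% of the called list genes, 72 of 78, were still lower and 76 were also called with all nuclei. Among all genes called in that fit, 1376 of 1541 were lower, so the direction was not particular to the lists. The median log2 fold change of all genes moved from -3.71 to -1.95 with equal numbers, and to -0.70 with no replicate block. The size of the fitted changes thus depended on the block. The fit on equal numbers tested 7123 genes instead of 9528, so its move cannot be laid to the number of nuclei alone. The labels give no cell class, so no biological explanation was tested.

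Exchanging the sides within drawn vectors gave 30 splits for each comparison, the real one included. For GABAergic-like against glutamatergic-like nuclei the real sides gave 19 list genes (1 of 30 splits gave as many, highest other 7). Non-neuronal-like against neuronal-like nuclei gave 129 (1 of 30, highest other 24). Striatal projection neuron-like against GABAergic-like nuclei gave 40 (1 of 30, highest other 20). A share of 1 of 30 is the smallest possible. The sides are clusters made from the RNA of the same nuclei, so more calls with the real sides were likely in advance. The splits therefore do not decide whether chance accounts for these calls. For library series S40326 against S40324 the real count is 0 genes by edgeR, which any split reaches, so the 30 of 30 splits (highest other 0) decide nothing. At an unadjusted p under 0.05 there were 586 genes, and DESeq2 called 948.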
